A study of Homo sapiens with 10 samples.

How the data were processed

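RNA was extracted with RNAzol RT from cells and exosomes of 5 prostate lines, per the labels, and hybridised in 1 colour (Cy3) to an Arraystar long noncoding RNA array made by Agilent, 1 array per line and fraction. The media held fetal calf serum per the labels, and exosomes were collected by ultracentrifugation. The authors scanned the arrays and read them with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09, genome build hg19 per the file headers). The deposited scanner files hold intensity per spot (gProcessedSignal, gMedianSignal and gBGMedianSignal, in scanner units) with flags of 0 or 1. The deposited value table holds log2 intensity for 14509 rows. Its rows could not be tied to the scanner values (Spearman's correlation at most 0.013 on any array), so it served for counts alone and no row of it is named.

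Spots flagged as non-uniform or as population outliers were left out, spots of a probe were averaged on the log2 scale, and 60297 of 60639 probes had a value on all 10 arrays. No spot was flagged as saturated. Each array's log2 gProcessedSignal was set to 0 at its 75th percentile over all transcript probes, and levels in the text are on this scale. A probe counted as detected when most of its spots carried the flag for signal well above background. Of 60 negative-control probes, which match no transcript, 2 to 8 also counted as detected in cells. In exosomes it was 12 in PNT2, 8 in VCaP and 0 to 3 in the other lines. Detection alone therefore does not show that a transcript is present, least of all in PNT2 exosomes. Detection ranged from 14511 to 47987 probes per array, and the number of arrays limits the precision. Of the columns given per sample, 0 were left unused.

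Groups came from the labels, cancer or normal line and cells or exosomes. Cells and exosomes of a line were paired, and their deviations from the fraction means correlated at 0.14 to 0.42 in the 5 lines. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and files were read with version 1.17.8 of data.table. Other tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Exosomes against cells used a term for each line and probes detected on at least 4 arrays. Cancer lines against PNT2 used probes detected in PNT2 or in all 4 cancer lines of that fraction, and the lone PNT2 array is assumed to vary like the cancer lines. Calls are Benjamini-Hochberg adjusted p under 0.05 within a comparison. A difference is given as at least a fold when arrays of the dimmer group were not above background, each such array entering at no less than its lowest detected level. Arrays of the brighter group that were not above background entered at their own value. Where there were such arrays, the fold is not a strict lower bound. Detection was compared with an exact sign-flip test and parent lines with an exact permutation over 120 pairings. The pipeline was tested on simulated data with 200 changed probes. For exosomes against cells in 5 lines it recovered 0%, 6.5% and 86% of changes of 1, 2 and 3 log2 units. With only 200 changed probes the correction is stricter than in the data of that comparison, where far more were called, so these shares are not the recovery there.

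Named probes followed a rule written before the data were examined. Where a comparison had calls, it took the 6 largest rises and 6 largest falls of coding genes and of noncoding transcripts, 1 probe per gene, among calls with 1 sign in every line. Otherwise it took 4 each way by the smallest p. Not every probe taken by the rule is described in the text or drawn. Of 65 RefSeq accessions among the names, 63 matched a gene. The 26 gene lists fixed beforehand could not be tested, since 0 had at least 5 named members, and long noncoding RNAs could not be set against mRNAs because the files do not give the class of most probes. Named probe groups, chosen after seeing the names, were tested with camera and fry, on 1 probe per HOX gene.

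Alternatives fixed before the data were examined were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, scaling to the median or to the 75th percentile of probes detected on all arrays, no filter, detection on every array, the authors' values as deposited, an intensity trend with robust estimation, no line term, the mean of a gene's probes and each line left out. Normexp used gMedianSignal because the files hold no gMeanSignal. Scan as a block, a common floor, pairs or arrays within 1 scan and the fit without the DU145 and PNT2 pairs were added after seeing the data. Scan order came from the file headers. The first scan held both PC3 arrays, the second the exosomes of DU145, LNCaP and PNT2, and the last one all other arrays. In DU145, LNCaP and PNT2, fraction therefore matches scan. For exosomes against cells with scan as a block, the PC3 and VCaP pairs alone set the difference. Outliers among the 4 cancer lines were sought with Dixon's ratio (critical value 0.829).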

Results

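RNA was measured in 5 established human prostate cell lines and in the exosomes that each line released into its medium, small vesicles collected by ultracentrifugation. DU145, LNCaP, PC3 and VCaP are prostate cancer lines, and DU145 came from a brain metastasis per the labels. PNT2 is normal prostate epithelium immortalised with SV40. Each line gave 1 array of cells and 1 array of exosomes, so the 10 arrays hold no repeat of a line, and lines serve as the replicates. The array carries probes for long noncoding RNAs and mRNAs. Of the 60297 probes kept, 58936 carry only an array identifier, and the 1361 named ones cover the HOX clusters, ultraconserved elements and a few control transcripts. The named genes below are therefore those that the files themselves name, and no probe is placed on a genome build here.

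Exosomes gave fewer detected probes than their parent cells in 5 of 5 lines. Cells of DU145, LNCaP, PC3, VCaP and PNT2 had 44889, 47987, 34732, 44092 and 47072 probes well above background, and their exosomes had 18562, 14511, 20655, 36851 and 27100. The mean difference, exosomes minus cells, was -20219 probes (SD 10238, n = 5 lines). An exact two-sided sign-flip test gave p = 0.0625, the smallest value that 5 pairs allow. HOX genes, the transcription factors that set position along the body axis, followed this loss of detection. Of their 92 exon probes, 36, 22, 30, 67 and 35 were detected in exosomes of DU145, LNCaP, PC3, VCaP and PNT2 (39.1% and 23.9% in the first pair), against 30.8%, 24.1%, 34.3%, 61.1% and 44.9% of all probes. In cells of these lines the exon probes stood at 89.1%, 91.3%, 67.4%, 85.9% and 80.4%, and all probes at 74.4%, 79.6%, 57.6%, 73.1% and 78.1%. The drop in percentage points was thus larger for HOX exon probes in every line, but probes of like signal were not compared. Of 38 HOX genes with an exon probe, each counted by its brightest exon probe, 32 to 38 were detected in cells, but 21, 13, 18 and 19 in the exosomes of DU145, LNCaP, PC3 and PNT2, and 33 in those of VCaP. By that probe, none of the 9 HOXD genes was detected in exosomes of DU145, LNCaP or PNT2, 1 was in those of PC3 and 8 in those of VCaP. Other probes of these genes could be, as HOXD11 intron 1 was detected in the exosomes of 3 lines, PNT2 among them. The 75th percentile of signal was 468, 388, 97.6, 217 and 422 scanner units in the cells of DU145, LNCaP, PC3, VCaP and PNT2. It was 16.5, 15.7, 21.1, 58.2 and 29.96 in their exosomes, so a probe missed in exosomes was not detectable at that signal rather than shown absent.

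**Figure D1:**
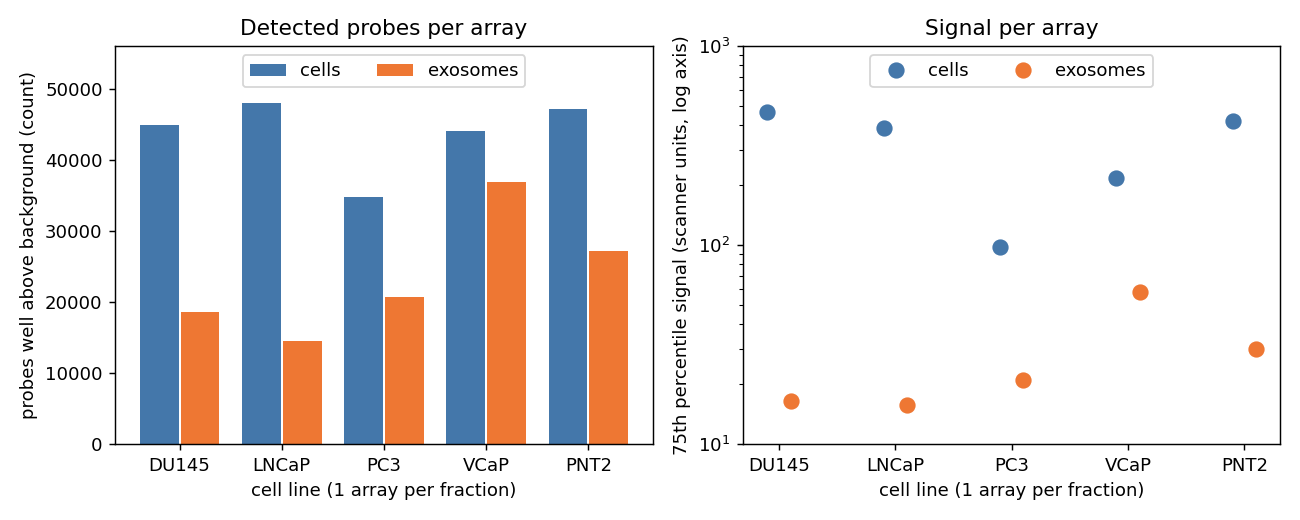
Probes well above background (left, count) and the 75th percentile of signal (right, scanner units on a log axis) for cells and exosomes of each line, 1 array per bar or point. Exosome arrays lie below the array of their parent cells in all 5 lines, and VCaP exosomes stand highest among exosomes with 36851 probes.

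The comparison of exosomes with parent cells over all 5 lines asks which transcripts take a larger or smaller part of exosomal RNA than of cellular RNA. Several transcripts of the minus strand of ultraconserved elements, genome segments shared without change between distant mammals, fell in exosomes. The element uc.63- was at least 4.4-fold lower (adjusted p = 0.0010, limma), above background in the exosomes of 1 line only. Elements uc.340-, uc.162- and uc.460- were at least 6.8-fold, 5.9-fold and 5.9-fold lower, each in 5 of 5 lines, and above background in the exosomes of 4, 4 and 2 lines. Among probes in HOX gene introns, HOXC4 intron 3 fell by 2.64 (SE 0.49, adjusted p = 0.0025) and HOXB3 intron 2 fell by 1.96 (SE 0.43, adjusted p = 0.0062), and both were above background on all 10 arrays.

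Falls of HOX exon probes were seen for HOXC6 exon 2, HOXB5 exon 2 and HOXC8 exon 2, at least 2.99-fold, 2.30-fold and 1.95-fold lower. Noncoding transcripts named after the HOX clusters fell as well, nc-HOXB9-195 at least 3.6-fold and nc-HOXC4-264 at least 3.4-fold. Each of these 5 probes was above background in the cells of all 5 lines and in the exosomes of 2 to 4. Their bounds are on the main scale. With scaling to probes detected on all arrays, falls called over all probes went from 5108 to 835.

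Whether rises or falls were more numerous depended on the scaling and the probes tested. Rises led on this scale, and with scaling to probes detected on all arrays (16787 against 835 falls). They were 4687 against 6739 falls with quantile normalization, 2626 against 3711 with normexp background correction, 5518 against 16420 with scaling to the median and 1159 against 2139 for probes above background on every array. Most of the named rises came from probes close to background in cells. The lowest detected signal was 9.92 to 14.2 scanner units in cells and 10.2 to 14.5 in exosomes, while the 75th percentile was far lower in exosomes. A probe at that lowest signal in both fractions thus reads as higher in exosomes, and the bounds below hold on this scale only. An exosome array not above background entered at its own value, so a fold with such an array is not a strict bound. This applies to uc.185+, uc.19-, uc.253-, AY034469, HOXB6 exon 1 and HOXD11 intron 1. The noncoding HOX transcript nc-HOXA13-101 was at least 31.9-fold higher in exosomes (adjusted p = 0.00075, limma), detected in the exosomes of 5 lines and in the cells of none. Transcripts uc.185+, uc.19- and uc.253- were at least 14.9-fold, 20.8-fold and 24.5-fold higher, with detection in the exosomes of 4 lines and in no cells. The probes nc-HOXC9-138 and AY034469 were at least 38.1-fold and 25.7-fold higher, detected in the cells of 4 lines and of 1. Among HOX gene probes detected in the cells of all 5 lines, HOXC8 intron 1, HOXA3 exon 4 and HOXA5 intron 2 were 22.3-fold, 14.7-fold and 13.7-fold higher. HOXB5 intron 2, HOXB6 exon 1 and HOXD11 intron 1 were at least 23.1-fold, 13.7-fold and 10.4-fold higher, detected in the cells of 3, 3 and 2 lines and in the exosomes of 5, 4 and 3. Each of the 12 was higher in 5 of 5 lines. In the same fit, 57 of 60 negative-control probes, which match no transcript, were also called higher, with a median log2 difference of 3.69.

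**Figure D2:**
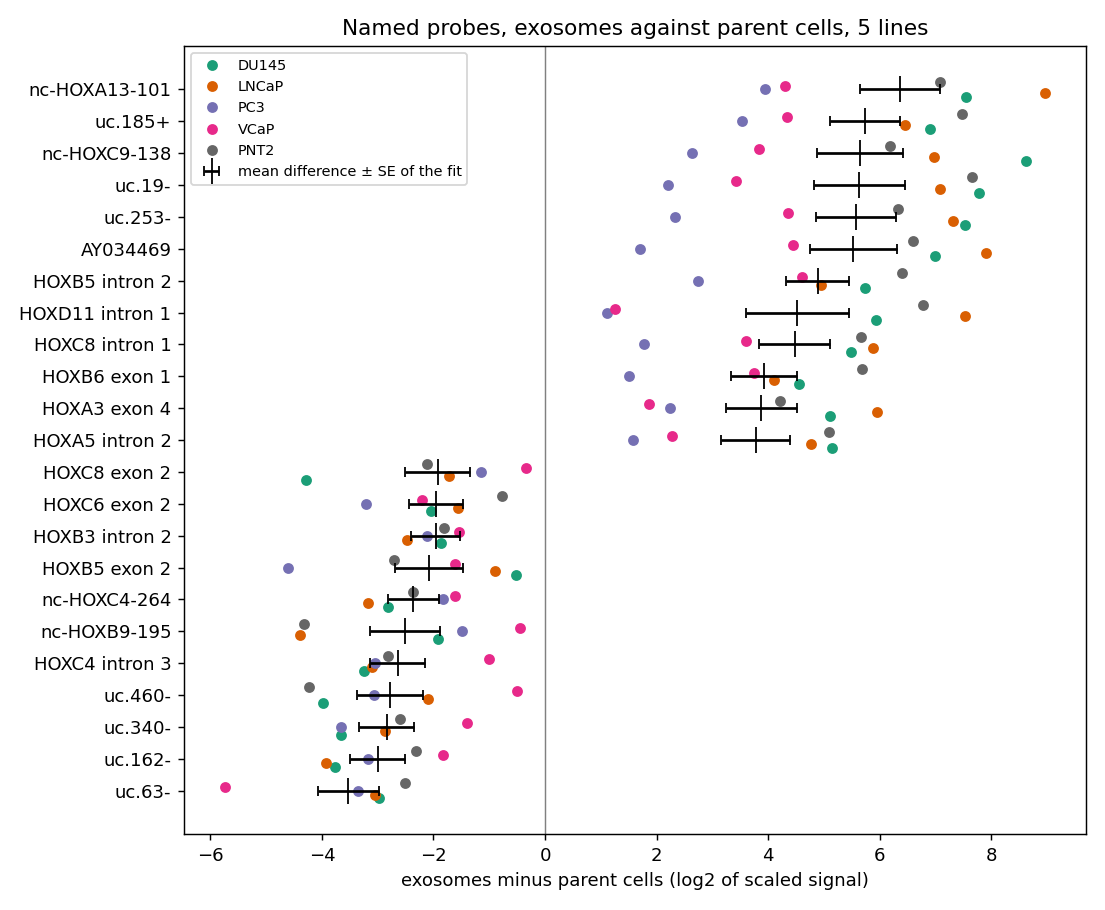
Log2 difference, exosomes minus parent cells, for 23 named probes of the comparison over 5 lines. Coloured points are single lines (1 array of each fraction), and bars give the fitted mean and its SE. The 12 rises run from 3.78 to 6.36 and are smaller in PC3 and VCaP than in the other lines for most probes, and the 11 falls run from -1.92 to -3.52. Arrays not above background enter at their own value, so these are not all measured differences.

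By group, 53 of 179 noncoding HOX probes were higher and 20 lower, against 10 and 9 of 79 HOX exon probes and 10 and 3 of 36 HOX intron probes. Of the ultraconserved elements, 55 of 209 minus-strand probes were higher and 18 lower, and 42 of 190 plus-strand probes were higher and 10 lower. Among the 20 control mRNAs, RPS18 and RPLP1, which encode ribosomal proteins, were 3.43-fold and 3.05-fold higher (adjusted p = 0.028 and 0.035), each in 5 of 5 lines and above background on all 10 arrays. RPL10, the other ribosomal protein mRNA named, was not called. It lay lower in exosomes of LNCaP, PC3, VCaP and PNT2 but not of DU145, and was above background in VCaP exosomes only. GAPDH and ACTB did not pass the test, with log2 differences of 0.16 and 0.76, which turned to -0.76 and -0.16 with scaling to the median. Of 21 other named noncoding or control probes, TncRNA, a transcript of the nuclear NEAT1 locus, fell by 1.84 (SE 0.52, adjusted p = 0.020), and mascRNA, a small RNA cut from MALAT1, and p53mRNA were at least 3.3-fold and 1.6-fold lower, above background in the exosomes of 3 and 2 lines. Beside AY034469, AY034470, lincRNA-RoR and lincRNA-p21 were higher, above background in the cells of 3, 3 and 2 lines and in the exosomes of 4 each. GRM4, a glutamate receptor, and Air were called higher as well, but were above background in the exosomes of 1 line only and in the cells of 5 and 4, so no rise was measured. RPS18, RPLP1, GRM4 and these other probes except AY034469 fall outside the rule for named probes in this comparison and were chosen after their values were seen. The calls of RPS18 and RPLP1 ended under quantile normalization (adjusted p = 0.60 and 0.86), with normexp (0.14 and 0.60), with scaling to the median (0.18 and 0.26) and with scan as a block (0.42 and 0.42). Both held with values under a common floor raised to it (0.019 and 0.022). That of TncRNA held with the floor (0.014) and with scan as a block (0.049), and ended with quantile normalization (0.12), with normexp (0.077) and with scaling to probes detected on all arrays (0.20). The last scaling ended those of mascRNA and p53mRNA too (0.23 and 0.41), and normexp those of mascRNA and lincRNA-p21 (0.090 and 0.066). With scan as a block the calls of mascRNA and p53mRNA were lost with the differences about as large (-1.94 and -1.60), and quantile normalization also ended that of p53mRNA (0.053). Scan as a block also ended the calls of lincRNA-p21, lincRNA-RoR and AY034470 (0.14, 0.066 and 0.076), with smaller fitted differences. That of AY034469 was smaller too, 8.4-fold with scan as a block (0.046) and 3.6-fold with normexp (0.047), both under the fold given above for the main scaling. Directions are on the scale of each array's 75th percentile, where the median of all probes tested was 0.06.

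Of 45233 probes tested with limma, 9223 were higher and 5108 lower in exosomes at an adjusted p under 0.05. Of the 9223, 1871 were above background in the exosomes of every line and 614 in none. Of the 5108, 5076 were above background in the cells of every line and 454 in the exosomes of none. The median log2 difference of all tested probes was 0.06, and other scalings set it between -0.87 and 0.97, so directions depend on the scaling. A test of 9 named probe groups (camera) found none past the threshold, with a smallest adjusted p of 0.23, or 0.67 with an estimated correlation, while fry, which compares no group with others, called 5. The 2 unnamed probes with the largest rise among those above background on all arrays were ASHG19A3A020488 and ASHG19A3A007946, with log2 differences of 5.57 and 5.56. ASHG19A3A044249 and ASHG19A3A019001 had the largest falls, -3.85 and -3.81. With values under a common floor raised to it, 305 of 11217 probes were higher and 3611 lower. The pairs of DU145, LNCaP and PNT2 had cells and exosomes in different scans. With scan as a block 1516 probes were higher and 779 lower. A fit of the PC3 and VCaP pairs alone, each within 1 scan, gave 0 calls (3597 at an unadjusted p under 0.05). Both fits take the difference from the PC3 and VCaP pairs, and the first takes its residual spread from all lines.

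In the 4 cancer lines alone, 4454 of the higher and 1986 of the lower calls were unnamed, and most named probes are HOX or ultraconserved ones. The element uc.63- was at least 4.1-fold lower in exosomes, where none of the 4 lines gave it above background (adjusted p = 0.0089). The probes uc.340-, uc.162-, uc.460- and nc-HOXC4-264, above background in the exosomes of 2 or 3 lines, were at least 7.1-fold, 6.1-fold, 4.6-fold and 3.2-fold lower. HOXC4 intron 3, uc.144- and HOXC6 exon 2, above background on all arrays, fell, with log2 differences of -2.60, -2.30 and -2.25. HOXB3 intron 2 fell from a mean level of 3.88 in cells (SD 0.58, n = 4) to 1.88 in exosomes (SD 0.94, n = 4). On the higher side, nc-HOXA13-101 was at least 26.0-fold higher. The probes nc-HOXC9-138, uc.162+, AY034469, uc.111- and nc-HOXD4-27 were at least 32.4-fold, 24.9-fold, 19.2-fold, 15.5-fold and 14.2-fold higher, detected in the cells of 3 lines for the first and of 1 for the rest, and in the exosomes of 3 or 4. HOXC8 intron 1, HOXA3 exon 4 and HOXA5 intron 2, detected in the cells of all 4, were 18.1-fold, 13.9-fold and 10.9-fold higher. HOXB5 intron 2, HOXB6 exon 1 and HOXD11 intron 1 were at least 17.7-fold, 10.2-fold and 7.5-fold higher, detected in the cells of 3, 3 and 2 lines and in the exosomes of 4, 3 and 2. All of these were alike in sign in 4 of 4 lines. For AY034469, nc-HOXD4-27, HOXB6 exon 1 and HOXD11 intron 1, exosome arrays not above background entered at their own value. Their folds are therefore not strict lower bounds. Of the groups, 29 of 163 noncoding HOX probes were higher and 5 lower, and 20 of 138 plus-strand ultraconserved probes were higher and 1 lower. Of 38616 probes tested with limma, 4529 were higher and 2003 lower. The number of calls changed with the lines kept. Without PC3 3239 were higher and 954 lower, and without VCaP 2849 and 1009. Without LNCaP 0 probes were called (6346 probes at an unadjusted p under 0.05) and without DU145 3, and 0 were left with normexp background correction (9183) or with scan as a block (8498).

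The comparison of the cancer lines with PNT2 asks what sets cancer apart from normal epithelium, with PNT2 as the single normal line. In cells, the named probes with the smallest p included 3 of the HOXC cluster. HOXC13 exon 2 was at least 110-fold higher in the cancer lines (mean log2 level 1.42, SD 1.14, n = 4, against -6.04 in PNT2), HOXC6 exon 2 was 123-fold higher and HOXC4 exon 4 was 121-fold higher. Among other probes of the cluster, HOXC5 exon 2 lay the same way, at 2.16, 0.02, 0.48 and 2.31 in DU145, LNCaP, PC3 and VCaP and -3.52 in PNT2. HOXC4 exon 2 did not, at 1.58, 2.60, 4.16 and 3.50 in DU145, LNCaP, PC3 and VCaP and 3.12 in PNT2. HOXD8 exon 2 was at least 36.2-fold higher. HOXA7 exon 2 lay the other way, at -0.82 (SD 0.29, n = 4) in the cancer lines and 5.64 in PNT2. The probes uc.127+, nc-HOXA6-72 and uc.208+ were also lower in the cancer lines, the first pair by at least 2.5-fold and 2.7-fold. Every one of these differences had 1 sign in 4 of 4 cancer lines, yet none passed the correction in limma. The smallest adjusted p among them was 0.084 for HOXA7 exon 2. It passed at 0.0092 when only probes above background on every array were tested, as did HOXC6 exon 2 at 0.016 and HOXC4 exon 4 at 0.020. HOXA7 exon 2 also passed at 0.046 with normexp, and HOXC13 exon 2 at 0.044 without VCaP. Over all 47188 probes, 0 passed, with 1390 at an unadjusted p under 0.05 and a smallest adjusted p of 0.065. In simulated data of the same design, 0% of probes changed by 3 log2 units were recovered.

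In exosomes, HOXC6 exon 2 was at least 11.9-fold higher in the cancer lines than in PNT2 (adjusted p = 0.64). HOXC13 exon 2 was at least 3.2-fold higher. PRAC1 exon 1 and ODC1, the latter encoding the enzyme that starts polyamine synthesis, had log2 differences of 3.38 and 2.97. HOXA7 exon 2, HOXB3 exon 4 and HOXB4 exon 2 were at least 11-fold, 7.3-fold and 4.8-fold lower, above background in the exosomes of 2, 2 and 1 of the cancer lines, and uc.408- was 8.3-fold lower. Each sign held in 4 of 4 cancer lines, and none of the 27154 probes passed the correction in limma (478 at an unadjusted p under 0.05, smallest adjusted p 0.26). HOXA7 exon 2 was above background in the exosomes of PNT2 and of 2 cancer lines, with levels of 5.26 in PNT2 and a mean of 1.45 (SD 3.07, n = 4) in the cancer lines. DU145 and VCaP exosomes, which detected it, stood much closer to PNT2, at 3.65 and 4.53. The fold above thus rests largely on LNCaP and PC3 exosomes, where it was not above background. In cells of DU145 and VCaP it was at -0.74 and -0.59, so it was bright in their exosomes but not in their cells. The cause was not tested. The named probe groups did not pass in either fraction, with smallest adjusted p of 0.059 in cells and 0.27 in exosomes (camera), or 0.99 and 0.42 with an estimated correlation.

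**Figure D3:**
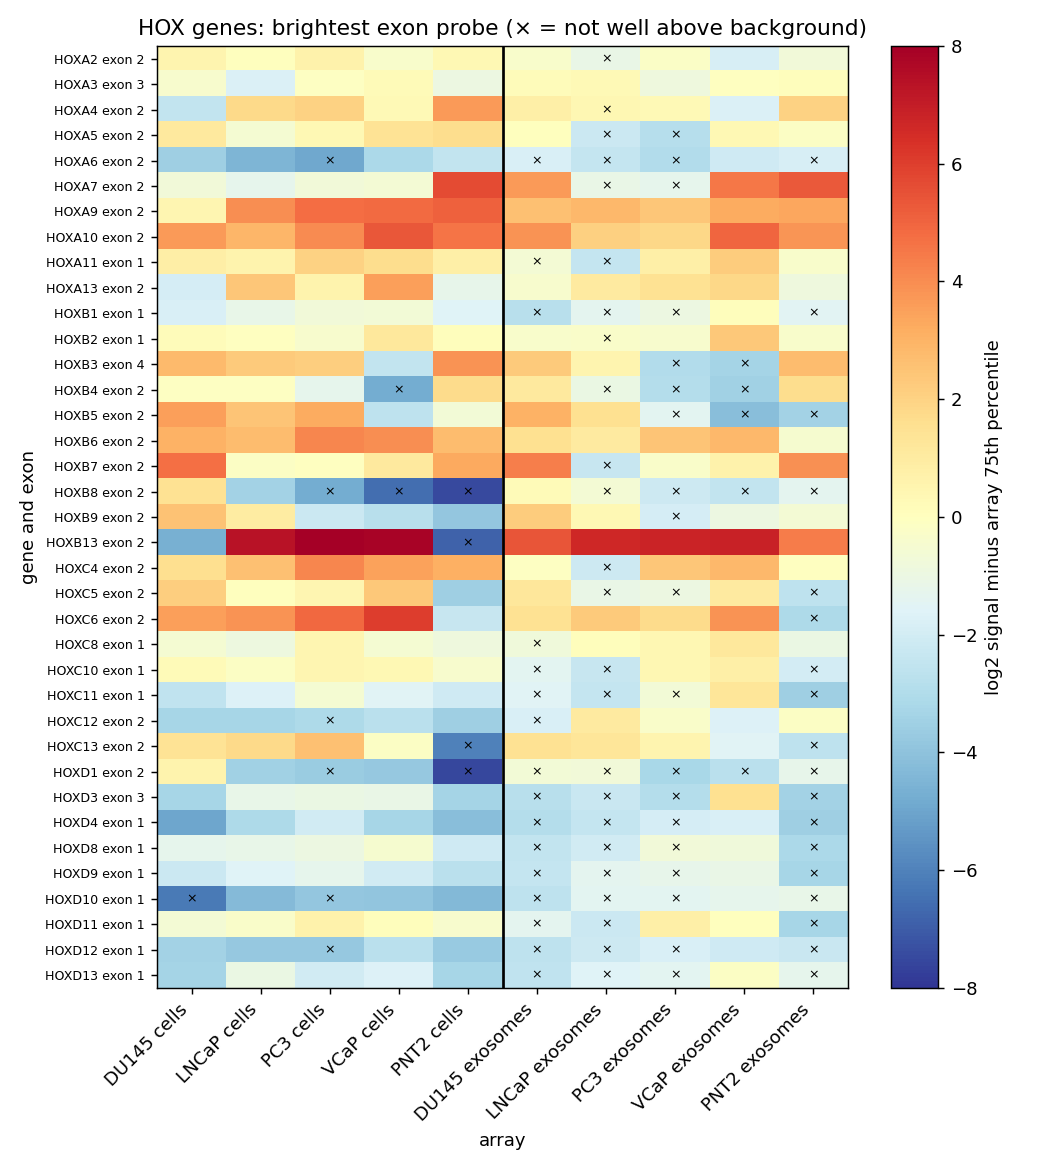
Level of the brightest exon probe of 37 HOX genes on each array, as log2 signal minus the array's 75th percentile (colour), with a cross where the probe was not well above background. Cells are left of the line and exosomes right. HOXA7 exon 2 is brightest in PNT2 cells at 5.64, and HOXD genes are crossed out in exosomes of DU145, LNCaP and PNT2.

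The test of whether the exosome shift differed between cancer lines and PNT2 compared exosomes minus cells in the 4 cancer lines with that in PNT2. Of 45233 probes 0 passed the correction in limma (730 at an unadjusted p under 0.05, smallest adjusted p 0.52). Among 9123 probes above background on every array, 14 passed, all lower in the cancer lines (219 at an unadjusted p under 0.05). Of the named probes with the smallest p, HOXC4 exon 4, HOXD8 exon 2, HOXC13 exon 2 and nc-HOXD1-46 were lower in the cancer lines, and uc.208+, HOXA9 exon 1, mascRNA and uc.24- were higher. Only mascRNA was above background in both PNT2 arrays. HOXD8 exon 2 and HOXC13 exon 2 were so in neither, HOXC4 exon 4, uc.208+, HOXA9 exon 1 and uc.24- not in PNT2 exosomes, and nc-HOXD1-46 not in PNT2 cells. The median of negative-control probes went from -6.89 in PNT2 cells to -2.40 in PNT2 exosomes, so the shift of an undetected probe there need not reflect transcript.

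HOXB13, a homeobox gene characteristic of prostate epithelium, and its genomic neighbour PRAC1 stood out in single lines and were chosen after their values were seen. HOXB13 exon 2 was bright in the cells of LNCaP, PC3 and VCaP, with log2 levels of 7.36, 8.28 and 7.83. It was at -4.67 in DU145 cells and not above background in PNT2 cells. In exosomes it reached 6.63, 6.77 and 6.82 in LNCaP, PC3 and VCaP, and 5.39 and 4.39 in DU145 and PNT2. PRAC1 exon 1 was at -2.77 and -2.52 in cells of DU145 and PNT2 and at 4.27 and 3.20 in their exosomes, against 7.88 to 9.02 in cells of the other lines. In DU145 and PNT2, HOXB13 exon 1 went from -2.28 and -2.29 to 1.52 and 1.43, and PRAC1 intron 2 from -4.90 and -4.85 to -0.28 and -1.32. These rises were smaller than those of the negative-control median, from -7.17 and -6.89 to -2.46 and -2.40. HOXB13 intron 2 rose by more, but of these arrays was above background in PNT2 exosomes only. HOXB13 exon 1 was above background in both fractions, at 47.6 and 80.9 scanner units in DU145 and PNT2 exosomes. The highest negative-control probes there were at 14.2 and 29.5. Over the 5 lines neither HOXB13 exon 2 nor PRAC1 exon 1 differed between fractions past the correction (adjusted p = 0.14 and 0.23, limma), being higher in exosomes in 2 lines and lower in 3. HOXB13 exon 2 did pass with scaling to probes detected on all arrays (adjusted p = 0.049). With scan as a block, where PC3 and VCaP alone set the difference, HOXB13 exon 2 and PRAC1 exon 1 were lower (log2 differences of -1.27 and -0.67, adjusted p = 0.74 and 0.82, limma). DU145 and PNT2, which carry the rise, had cells and exosomes in different scans and do not enter that difference.

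**Figure D4:**
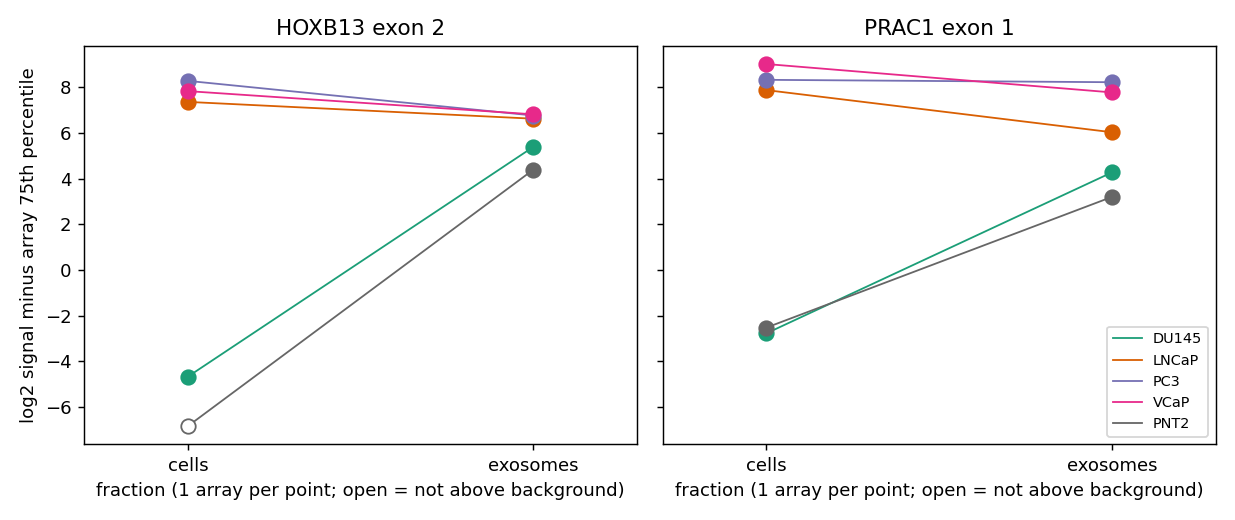
Level of HOXB13 exon 2 and PRAC1 exon 1 in cells and exosomes of each line, as log2 signal minus the array's 75th percentile, 1 array per point. For HOXB13, DU145 and PNT2 lie at -4.67 and -6.84 in cells and at 5.39 and 4.39 in exosomes, while the other 3 lines start above 7.

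Once the mean of each fraction was removed, exosomes resembled their own parent line more than the other lines. With each fraction's mean removed from every probe, the exosome arrays of 5 of 5 lines correlated best with the cells of their own line over 45233 probes. Pearson's r across probes, which are not independent replicates, was 0.28, 0.25, 0.14, 0.42 and 0.28 for DU145, LNCaP, PC3, VCaP and PNT2. The mean r was 0.28 with the own parent and -0.07 with other parents, and an exact one-sided permutation test over the 120 pairings gave p = 0.0083. The PC3 and VCaP pairs each lay within 1 scan, so a match there can also come from scan, which the pairings do not take into account. In DU145, LNCaP and PNT2, cells and exosomes were in different scans. PC3 exosomes had the smallest gap between their own parent and the next, with a next highest r of 0.13, and over probes above background on every array they correlated best with LNCaP cells. Without removal of the means, over the latter probes, Pearson's r of DU145 and LNCaP exosomes was highest with PC3 cells (0.86 and 0.78, own cells 0.84 and 0.75). That of PNT2 exosomes was highest with VCaP cells (0.82, own cells 0.81). Spearman's correlation there was highest with the own cells in every line.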

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

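All tests of explanations in this part were chosen after the result was seen, except the counts of other splits of the arrays.

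HOXB13 exon 2 stood far from the other cancer lines in DU145 cells, at -4.67 against 7.36 to 8.28, and in DU145 exosomes, at 5.39 against 6.63 to 6.82. PRAC1 exon 1 did so in DU145 cells, at -2.77 against 7.88 to 9.02. Other levels apart from the rest of the 4 cancer lines were AY034469 in PC3 cells (-2.88), ODC1 in LNCaP exosomes (6.76), and HOXB3 exon 4 (-2.50), HOXC4 exon 4 (4.49) and mascRNA (2.74) in VCaP cells. The 75th percentile of signal in VCaP exosomes, 58.2 scanner units, stood apart from 15.7 to 21.1 in the other cancer exosomes. These are 9 of 122 groups tested, and chance alone gives about 1 in 20. A spike-in control probe outside every comparison reached 508 scanner units in DU145 cells, above the 73.1 of the highest negative-control probe there. The highest spike-in probe also stood above the highest negative-control probe in the cells of every other line and in the exosomes of PC3 and VCaP.

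HOXB13 exon 2 and PRAC1 exon 1 were bright in the exosomes of DU145 and PNT2 but not in their cells. HOXB13 exon 1 and PRAC1 intron 2 rose by less than the negative-control median there. In both exosome arrays HOXB13 exon 1 still lay above the highest negative-control probe, and PRAC1 intron 2 below it. Signal at the level of the negative controls was excluded for HOXB13 exon 2 and PRAC1 exon 1, since the 4 exosome signals were at least 9.32 times the highest negative-control probe of their array. Probes of the own line that LNCaP cells lack were kept (13 of 19 in DU145 and 19 of 21 in PNT2, against 1 and 0 in LNCaP exosomes, larger Fisher's exact p = 0.00011). This argues against LNCaP arrays under these labels, though LNCaP exosomes had the fewest detected probes, 14511. The test took the same probes on both arrays as independent sets. Here and in the next test, probes of single arrays are not replicates, so p does not measure the spread between preparations. An array of PC3 or VCaP, or an exchange of DU145 and PNT2, was not tested in this way. RNA of another line may have been in these preparations: of probes absent from the own cells, those bright in LNCaP but not VCaP cells were detected more often than those bright in VCaP alone (13 of 28 against 8 of 47 in DU145, Fisher's exact p = 0.0084, and 16 of 22 against 12 of 51 in PNT2, p = 0.00015). In DU145 exosomes, probes bright in LNCaP but absent from the own cells lay at -1.36 relative to LNCaP exosomes (median, quartiles -1.78 and -0.82). In PNT2 exosomes they lay at -2.02 (-2.43 and -1.49). HOXB13 exon 2 was within both ranges, at -1.23 and -2.23, and PRAC1 exon 1 in DU145 only (-1.76 and -2.83). HOXB13 exon 2 was also within the wider quartiles relative to PC3 and VCaP exosomes. Selective export of HOXB13 from cells that hold little of it stays open and was not tested.

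More probes were higher than lower in exosomes over the 5 lines, 9223 against 5108. A candidate explanation is that probes near background take a higher scaled level on the dimmer exosome arrays. Put through the same fit, 57 of 60 negative-control probes were called higher, which this explanation needs. With values under a common floor raised to it, 305 probes were higher. Export of dim transcripts stays open for those, and was not tested apart from this.

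The 5108 falls could come in part from the difference between the second and the last scan, which separate exosomes from cells in DU145, LNCaP and PNT2. Of 4363 probes called lower from those 3 pairs, 72.2% in PC3 and 78.6% in VCaP lay below the median of all probes in pairs held within 1 scan. Random probes of the same signal in cells gave a median of 69.8% and 70.1%, so most of that share goes with brightness, and the smaller excess over the highest random list was 0.871 percentage points. Scan cannot be told apart from fraction in these 3 lines, and what keeps it open is that the excess is small in PC3. A lower share of these transcripts in exosomes was not tested in any other way.

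Lines pair the arrays, so the number of calls is held against splits that part every pair of cells and exosomes. Over 5 lines, 1 of 16 such splits gave as many calls as the real 14331 and the highest other gave 0, and in the 4 cancer lines 1 of 8 gave as many as the real 6532 and the highest other gave 0. Both are too few for a share under 0.05. Among splits of any kind, which also include those that leave pairs unparted, 1 of 100 taken from 126 possible and 1 of 32 gave as many, with highest others of 11242 and 2904. These set the cells of the lines whose pairs span scans, with both PC3 arrays, against the rest. With a term for each line, the unparted PC3 and VCaP pairs set no part of the difference. Both highest others are thus the same comparison, exosomes against cells, from the remaining pairs, where fraction matches scan. They show the calls of those pairs alone and no other grouping.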

How the results depend on the processing

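Scan as a block, the common floor, pairs or arrays of 1 scan, the fit without the DU145 and PNT2 pairs and the probe group tests were chosen after seeing the data, and the other alternatives before. Over 5 lines, calls higher and lower were 9223 and 5108. They were 2626 and 3711 with normexp, 4687 and 6739 with quantile normalization, 5518 and 16420 with scaling to the median, 16787 and 835 with the percentile of probes detected on all arrays, 23453 and 5603 with no filter, 1159 and 2139 for probes above background on every array, 0 and 0 in the authors' value table (2311 at an unadjusted p under 0.05) and 8374 and 3138 with no line term. With scan as a block they were 1516 and 779, with the common floor 305 and 3611, with pairs within 1 scan 0 and 0, and without the DU145 and PNT2 pairs 3 and 0. Leaving out 1 line gave 4529 to 8789 higher and 2003 to 5641 lower, and PNT2 (4529 and 2003), LNCaP (5130 and 2141) and DU145 (5948 and 3145) moved a count by over 1.5 times. In 4 cancer lines, 4529 and 2003 became 0 and 0 with normexp, 1249 and 1091 with quantile normalization, 3030 and 11150 with the median, 10186 and 236 with the detected percentile, 19713 and 2739 with no filter, 927 and 1321 on every array, 0 and 0 in the value table, 3646 and 740 with no line term, 0 and 0 with scan as a block, 118 and 1829 with the common floor and 0 and 0 within 1 scan. Leaving out 1 line gave 0 to 3239 higher and 0 to 1009 lower (0 and 0 without LNCaP, 3 and 0 without DU145, 3239 and 954 without PC3, 2849 and 1009 without VCaP). No call shared with the values first given changed direction under any of these.

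Cancer lines against PNT2 in exosomes gave 0 calls, but 1 on every array, 12 with an intensity trend, 4 with scan as a block, 4 with arrays of 1 scan and 0 to 21 with 1 line left out (21 without DU145). In cells, 0 became 6 with normexp, 38 on every array, 8 with an intensity trend and 0 to 14 with 1 line left out (7 without DU145, 14 without LNCaP, 14 without VCaP). The shift in cancer lines against PNT2 went from 0 to 14 on every array. With fraction means removed, exosomes matched best with their own parent in 5 of 5 lines, in 3 with no filter and in 4 on every array. The mean difference in detected probes lay between -23463 and -16904 with 1 line left out and was -10837 with another detection flag. Named probes taken by the rule kept their direction in all alternatives of the comparisons of exosomes with cells. Of probes outside it, HOXB13 exon 2 and PRAC1 exon 1 turned with scan as a block, where PC3 and VCaP alone set the difference, from 3.60 to -1.27 and from 1.92 to -0.67. GAPDH turned from 0.16 to -0.76 with scaling to the median and ACTB from 0.76 to -0.49 with quantile normalization. In 5 lines, 281 pairs of a probe and an alternative kept the call and 74 lost it, and in 4 cancer lines 149 kept and 134 lost it. The causes were not tested, except that fewer probes or lines enter some fits. Exosome arrays had 14511 to 36851 probes detected, and whether signal over background limits the rest was not tested.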

Other observations

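Few ultraconserved elements were above background on all 10 arrays, 16 of 480 probes of the minus strand and 7 of 479 of the plus strand, against 9123 of all 60297 probes. The brightest was uc.46-, at a mean log2 level of 7.03 in cells (SD 0.51, n = 5) and 5.84 in exosomes (SD 1.02, n = 5), followed by uc.420- (6.01 and 4.30) and uc.141- (5.58 and 4.22). Among the 16 minus-strand probes, 6 fell in exosomes and 1 was higher, with a median log2 difference of -1.31 against -0.64 for all 9123 probes above background everywhere. As a group they missed the threshold with camera (adjusted p = 0.059, or 0.40 with an estimated correlation), while fry, which compares no group with others, gave 0.013 and camera gave 0.024 with scaling to probes detected on all arrays. The element uc.144- fell by 2.28 on the log2 scale (SE 0.44, adjusted p = 0.0032, limma) in 5 of 5 lines.

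Over the 9123 probes above background on all arrays, cells of LNCaP and PC3, and cells of DU145 and PNT2, correlated at a Pearson's r of 0.93 across probes. The highest of all pairs of arrays was 0.96, between exosomes of DU145 and PNT2, and the lowest was 0.68. In the authors' value table, array medians lay between 5.29 and 5.85 on the log2 scale, and 14376 of its 14509 row names are names of probes on the array, with a Spearman's correlation to the scanner signal of the same name of at most 0.013.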
